A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

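Small RNA libraries of rainbow trout (Oncorhynchus mykiss) intestine were grouped by the treatment stated in the labels, M199 injection (control) or IHNV injection, with 3 libraries per group taken at 48 h. Per the labels' protocols, total RNA was extracted with Trizol, RNA of 18 to 30 nt was selected on a polyacrylamide gel, and libraries were made by standard Illumina protocols. The aligner, the miRNA database, the genome build and the counting rule are not given in the sources used here, so no coordinates are printed. Nothing in the labels says that the libraries came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical.

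The deposited counts are whole read counts per miRNA name, per the file headers. The deposited TPM values are each count as its part of a library total on the usual TPM scale, with no length term, and a count of 0 is written as 0.01. The sum of the counts exceeds the total implied by TPM by 1.34% to 1.83% of that total, so some reads stand in more than 1 row. The authors also deposited group means, a log2 fold change that equals the log2 ratio of those means, and a p-value with its FDR from a test that is not named. The table has 1430 rows with 1171 distinct sequences; 439 rows share their sequence with another row, and 28 predicted rows share at least 18 nt with a known one, so reads of such rows could have been split or counted more than once. Library totals ranged from 9531263 to 14006872 counts. A floor of 3 counts corresponded to 0.218 to 0.319 TPM. For miR-21-y the exact 95% interval of the count in control replicate 3 was 873 to 911 CPM (counts as deposited over their sum); such intervals cover counting error only, since reads are not independent molecules.

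Rows with at least 1 CPM in at least 3 libraries were tested, 579 in all (352 known and 227 predicted, 504 distinct sequences). The design written before the data were examined named limma-trend on log2(TPM + 1) unless the table also held counts. Because it did, the main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, group as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as the fold change over the square root of its F value. limma-trend (limma 3.58.1) and DESeq2 1.42.0 were alternatives. The biological coefficient of variation was 21.3%.

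The 13 miRNA lists were fixed by family name before the data were examined: antiviral and inflammatory, leukocyte, erythroid, intestinal epithelium, pancreas and endocrine, smooth muscle and stroma, striated muscle, neural and sensory, miR-17-92 and paralogous clusters, let-7 with miR-100 and miR-125, liver, endothelium, and hypoxia. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the lists, then again with an estimated correlation and with fry. Arm ratios were log2((5p TPM + 1)/(3p TPM + 1)) of names with both arms tested, compared with limma and adjusted over 89 names. The suffixes -x and -y were read as 5p and 3p from the sequences of known miRNAs.

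Predicted miRNAs are given by sequence. The text names the 6 higher and 6 lower miRNAs past the threshold with the largest change and a mean of at least 10 TPM, filled up by smallest unadjusted p where too few passed (here all 12); the 5 most abundant miRNAs; in each list the most abundant member and the one with the smallest p; and the 2 arm ratios with the smallest p. Others are named only where stated as chosen after their values were seen, or where they make up a count of 5 or fewer.

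The tests were checked on simulated counts for the IHNV against M199 comparison with 579 miRNAs, 200 of them changed. edgeR recovered 25.4% of 1.5-fold, 70.1% of 2-fold and 98.5% of 4-fold changes, with 5 false calls among 134. DESeq2 recovered 26.9%, 67.2% and 95.5%, with 4 false calls among 130. limma-trend on totals alone made 153 false calls among 284, because changed abundant miRNAs shifted all others by a median of -0.54 on the log2 scale; after median-of-ratios scaling it made 3 among 130. A simulated list shifted by 1 on the log2 scale was recovered with 0 false lists, and 9 of 10 arm ratios shifted by 2 were recovered with 0 false ones. In the simulation the changed rows held 69.2% of the counts, rows varied independently and no library stood apart. With fewer changed rows the adjusted threshold is harder to pass, so these rates can overstate the power in the real data. Members of real lists can vary together, with an estimated correlation of 0.426 for the leukocyte list.

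Alternatives covered the pseudocount (0.1 and 10), the filter, the scaling, the variance prior, known rows only, the sum of rows of the same family and arm, a replicate block and leaving out each library. For that sum, 69 of the 157 -z rows were added to the -x or -y row of their name with which they share at least 18 nt, a rule set after the data were seen. Added after the data were seen were collapsing identical sequences, scaling by library totals only, robust quasi-likelihood fitting, camera with an estimated correlation without control replicate 3, and leaving out 53 families described in mammals, alone or with control replicate 2. Figures were drawn with matplotlib 3.10.9.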

Results

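Small RNA was sequenced from the intestine of rainbow trout 48 h after an intraperitoneal injection. Fish of one group received infectious hematopoietic necrosis virus (IHNV), a rhabdovirus of salmonids, and fish of the control group received M199, a cell culture medium. Each group had 3 libraries, numbered 1 to 3. The deposited table held 1430 miRNA rows, of which 576 carried names of known miRNAs and 854 were predicted ones, given here by their sequences. The counts of a library summed to between 9531263 and 14006872. Names ending in -x and -y stand for the 5p and 3p arms of a hairpin, and -z marks rows whose arm the table leaves open.

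A few miRNAs held most of the counts in both groups. miR-192-x, an abundant miRNA of the intestinal epithelium, took 26.8% ± 5.0 (SD, n = 3) of the counts in controls and 26.6% ± 1.14 (SD, n = 3) after IHNV. miR-143-y, typical of smooth muscle and stroma, took 18.8% ± 0.634 (SD, n = 3) in controls and 21.1% ± 1.06 (SD, n = 3) after IHNV, with no overlap between the groups (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). The top 10 rows together took 75.1% ± 0.905 and 75.2% ± 0.482 (SD, n = 3). By edgeR, miR-192-x differed by a log2 fold change of -0.04 (SE 0.12), miR-143-y by 0.13 (SE 0.10), miR-199-x by -0.11 (SE 0.16), miR-26-x by 0.07 (SE 0.09) and miR-21-x by -0.44 (SE 0.16). Without control replicate 3 these were -0.17, 0.18, 0.10, 0.07 and -0.24 in the order given. None of these 5 most abundant miRNAs passed the test.

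The first comparison asked which intestinal miRNAs differ after IHNV injection, the study's stated subject being immune regulation against this virus in the intestine. The smallest p belonged to miR-21-y, the 3p arm of miR-21, a miRNA induced in many inflamed tissues. Its level was 1422 ± 463 TPM in controls and 3692 ± 104 TPM after IHNV (SD, n = 3), a log2 fold change of 1.35 (SE 0.21, edgeR adjusted p = 0.0897). miR-183-x and miR-96-x, which come from 1 cluster known from sensory cells, stood at 50.0 ± 9.96 and 25.7 ± 5.31 TPM in controls against 96.5 ± 16.6 and 41.5 ± 5.26 TPM after IHNV (SD, n = 3). miR-203-y, a miRNA of differentiating epithelia, stood at 62.8 ± 19.3 against 28.4 ± 11.1 TPM (SD, n = 3). miR-144-x, the less abundant arm of an erythroid miRNA, stood at 14.2 ± 1.92 against 8.89 ± 0.989 TPM (SD, n = 3). Its main arm, miR-144-y, had a log2 fold change of -0.22. No miRNA passed an adjusted p of 0.05 in the edgeR test of 579 rows.

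**Figure D1:**
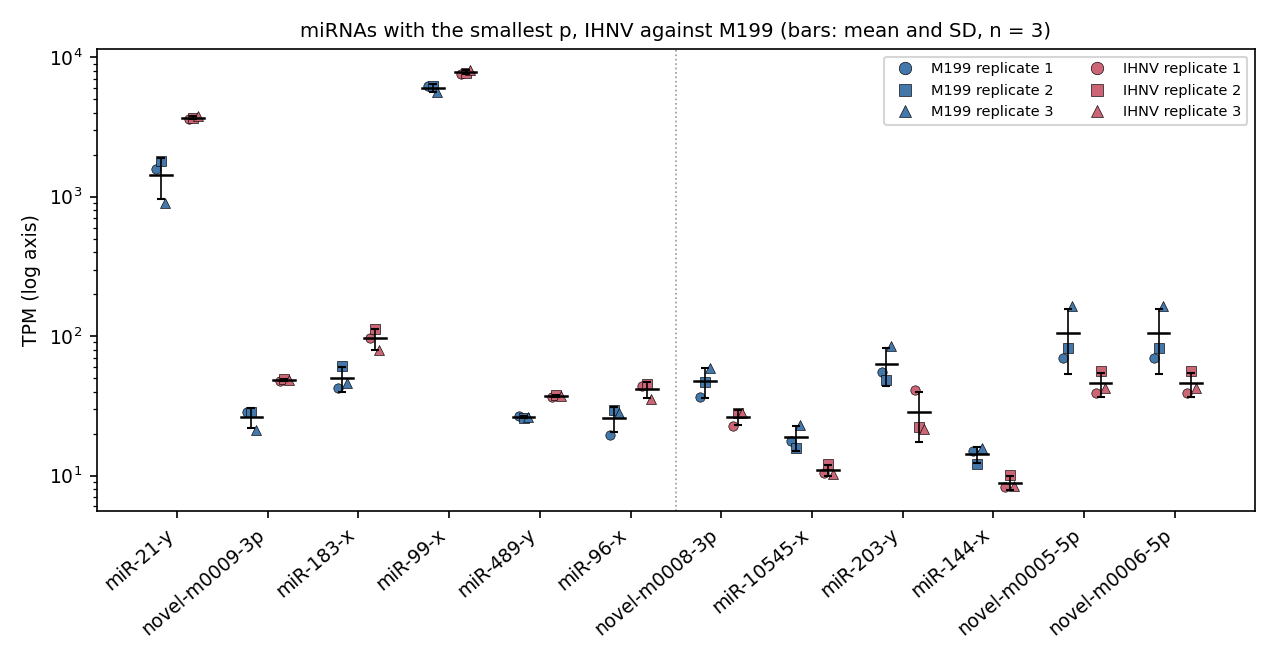
TPM of each library (log axis) for the 6 miRNAs with higher and the 6 with lower values after IHNV that had the smallest p among rows with a mean of at least 10 TPM. Predicted rows carry their table names, points are libraries, lines and bars are the mean and SD of 3 libraries. The 3 infected libraries of miR-21-y lie between 3590 and 3798 TPM and its control libraries between 903 and 1794 TPM.

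By edgeR, 0 of the 579 rows passed and 104 rows had an unadjusted p under 0.05, 55 of them higher and 49 lower after IHNV (90 distinct sequences), where chance alone gives 28.95. DESeq2 called 21 rows, 8 higher and 13 lower, which hold 7 and 8 distinct sequences, and limma-trend on log2(TPM + 1) called 0, with 106 rows under an unadjusted p of 0.05. The authors' deposited table lists 25 rows with an FDR under 0.05, 10 higher and 15 lower (9 and 9 distinct sequences), by a test it does not name. Of the 21 rows called by DESeq2, 20 are among those 25. The groups did not overlap in TPM for 158 rows (27.3%), where chance gives 10%.

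Besides miR-21-y, miR-183-x and miR-96-x, the higher rows with the smallest p among those with a mean of at least 10 TPM were a predicted miRNA, miR-99-x and miR-489-y. The predicted miRNA CCTGGATGTGGGTTCCGTCTCC stood at 26.2 ± 4.18 TPM in controls and 48.3 ± 0.655 TPM after IHNV (SD, n = 3), a log2 fold change of 0.85 (SE 0.15, edgeR adjusted p = 0.10). Its 22 nt begin with all 20 nt of miR-462-y (CCTGGATGTGGGTTCCGTCT), the 3p arm of a fish miRNA known for induction by interferon. The row may thus be a longer form of miR-462-y, and reads of the 2 rows may have been split by the counting. The antiviral and inflammatory list, the miR-462 arm ratio and the sum of rows of the same family and arm leave this predicted row out. miR-99-x had a log2 fold change of 0.33 (SE 0.09), miR-489-y of 0.45 (SE 0.13), miR-183-x of 0.91 (SE 0.18) and miR-96-x of 0.65 (SE 0.20), with edgeR adjusted p from 0.110 to 0.18. All 3 infected libraries lay above all 3 controls for each of these 6 miRNAs.

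Among rows with a mean of at least 10 TPM, the lower rows with the smallest p were the predicted CCAGTATGGCTTGTGCTGCTAAC at a log2 fold change of -0.90 (SE 0.21), miR-10545-x at -0.82 (SE 0.20), miR-203-y at -1.19 (SE 0.31), miR-144-x at -0.71 (SE 0.19) and the predicted ACCCTGTAGAACCGAATTTGTGTT, listed in 2 rows with the same counts, at -1.25 (SE 0.33), each with an edgeR adjusted p of 0.160. The former predicted miRNA shares at least 18 nt with miR-457-y and the latter with miR-10-x, so their reads may have been split or counted in both rows. All 3 infected libraries lay below all 3 controls for each of these rows. Without control replicate 3 all 5 changes were smaller, at -0.68, -0.63, -0.89, -0.62 and -0.74 in the order given. The last stood at 69.3, 81.5 and 163 TPM in control replicates 1, 2 and 3.

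Leaving out control replicate 2 gave 40 edgeR calls, 33 higher and 7 lower (32 and 5 distinct sequences), and leaving out control replicate 3 gave 1, miR-21-y, with a log2 fold change of 1.12. miR-21-y passed in 8 of 23 alternative settings, among them the sum of rows of the same family and arm (adjusted p = 0.0381; planned, but with its rule for -z rows set after the data were seen), and its log2 fold change lay between 1.12 and 1.55 in all 23, with adjusted p from 3.59e-05 to 0.350.

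Among the 33 rows called higher without control replicate 2, 17 belonged to 53 families described in mammals and, from general knowledge, not in fish; this list was written after those calls were seen. The tested rows of these families numbered 43, and all 43 had a positive log2 fold change, with a median of 0.65. Their summed level was 189, 370 and 186 TPM in control replicates 1, 2 and 3 and 428, 414 and 381 TPM in infected replicates 1, 2 and 3. With these families left out, edgeR called 0 of 536 rows, with 86 under an unadjusted p of 0.05, and in a refit with control replicate 2 left out as well it called 13, 10 higher and 3 lower, the last being 1 distinct sequence. DESeq2 and the authors' deposited table each list 2 of these rows, miR-378-z and miR-452-x, which were named after their values were seen.

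The second comparison asked whether miRNAs of known cell types and responses differ as groups. Of 11 lists with at least 3 tested members, 0 passed an adjusted p of 0.05 by camera, and 1 had an unadjusted p under 0.05. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05, while fry, which asks whether a list moves on balance and not whether it stands apart from other miRNAs, gave the neural and sensory list an adjusted p of 0.0191. In fry's mixed test, which takes changes in either direction, the adjusted p was 0.00720 for the striated muscle list. It was 0.00720 for the neural and sensory list and 0.0113 for the intestinal epithelium list. The words "adjusted over the list alone" below mean that the edgeR p-values were adjusted within a list.

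The antiviral and inflammatory list (miR-462, miR-731, miR-146, miR-155, miR-21, miR-132, miR-212, miR-221 and miR-222) had 21 tested members, 10 with positive and 11 with negative log2 fold changes. None passed over all miRNAs, and 1, miR-21-y, passed when adjusted over the list alone (edgeR adjusted p = 0.00325). miR-462-x, the main arm of the interferon-induced miR-462, had a log2 fold change of 0.01 (SE 0.11) and miR-462-y of 0.62 (SE 0.22). miR-155-x, known from activated lymphocytes and macrophages, stood at 73.1 ± 10.1 TPM in controls and 73.4 ± 3.46 TPM after IHNV (SD, n = 3). miR-146-y, the less abundant arm at a mean of 126 TPM, had a log2 fold change of 0.39 (SE 0.14). The main arm miR-146-x, at a mean of 34940 TPM, had -0.32. miR-221-y had a log2 fold change of -0.59 (SE 0.20) and miR-222-x of -0.36 (SE 0.14). The list's median log2 fold change was -0.03 and its mean 0.05, and the camera adjusted p was 0.640 in the higher direction, so the median differed in sign from the mean and the test. The members named here beyond miR-21-x and miR-21-y were chosen after their values were seen, as were miR-144-y, miR-194-x, miR-200-y, miR-486-x, miR-486-y, miR-182-x and miR-122-y.

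The leukocyte list had 9 tested members, 6 of them negative, and 0 passed over all miRNAs or adjusted over the list alone, with 2 at an unadjusted p under 0.05 by edgeR. Its most abundant member, miR-181-x, had a log2 fold change of -0.19 (SE 0.11; -0.10 without control replicate 3) and miR-181-y, with the smallest p, of -0.27 (SE 0.11); the list's camera adjusted p was 0.402. Of 6 erythroid members, 2 passed when adjusted over the list alone by edgeR, miR-144-x (adjusted p = 0.0282) and miR-451-x (adjusted p = 0.0306), the latter at 355 ± 61.5 TPM in controls and 266 ± 9.54 TPM after IHNV (SD, n = 3). The main arm miR-144-y, at a mean of 214 TPM, had a log2 fold change of -0.22. miR-486-x and miR-486-y of the same list had positive log2 fold changes of 0.64 (SE 0.35) and 0.40 (SE 0.41), and the list's camera adjusted p was 0.413. Its median log2 fold change of -0.26 lay between -0.45 and -0.0276 over the alternatives, the latter without control replicate 1 and the former without control replicate 3.

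The intestinal epithelium list had 18 tested members, 6 positive and 12 negative, and its camera adjusted p was 0.358 with a median log2 fold change of -0.06. Adjusted over the list alone, 3 members passed by edgeR, miR-203-y, miR-194-z and miR-200-x, with log2 fold changes of -1.19, -0.80 and -0.39. The ratio of miR-194-z to miR-194-x was at most 0.000118 in any library, and miR-194-x, at a mean of 38977 TPM, had -0.09. miR-200-x, at a mean of 349 TPM, is the less abundant arm, and miR-200-y, at 24299 TPM, had 0.00691. The list sat lower in control replicate 3 than in the other controls, where 16 of its 18 members were below the mean of those controls, at a median log2 ratio of -0.40. Without control replicate 3 the list was lower after IHNV with a camera adjusted p of 0.00239 and a median log2 fold change of -0.17, but with an estimated correlation in that same fit its adjusted p was 0.407.

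The neural and sensory list had 13 tested members, 9 positive and 4 negative, with a median log2 fold change of 0.19 (0.11 to 0.32 over the alternatives, the latter without control replicate 1), and its camera p of 0.0304 became 0.335 after adjustment and 0.783 with an estimated correlation. The members with the smallest p were miR-183-x, which alone passed when adjusted over the list alone (edgeR adjusted p = 0.0110), miR-96-x and miR-182-x, and the most abundant, miR-128-y, stood at 1727 ± 348 TPM in controls and 2076 ± 29.7 TPM after IHNV (SD, n = 3). Its log2 fold change was 0.23, and 0.0917 without control replicate 3. In the striated muscle list 2 of 7 members passed when adjusted over the list alone by edgeR, miR-206-y at a log2 fold change of -1.22 (SE 0.27) and miR-133-x at -1.07 (SE 0.28), both under 10 TPM in either group, so that the former was -0.41 with limma-trend on log2(TPM + 10), while the abundant miR-1-z had -0.01 (SE 0.11) and the list a camera adjusted p of 0.402. For the smooth muscle and stroma list, with 6 of 11 members positive, the camera adjusted p was 0.942, the median 0.12 and the mean -0.09; miR-199-z had the smallest p at a log2 fold change of 0.63 (SE 0.26).

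The miR-17-92 and paralogous clusters list, which holds proliferation-linked miRNAs, had 14 of 18 members negative, a median log2 fold change of -0.21 and a camera adjusted p of 0.358. Without control replicate 3 these were -0.0853 and 0.485. Its smallest p belonged to miR-20-x at -0.57 (SE 0.17), and miR-92-y, the most abundant, had -0.10 (SE 0.09). For the pancreas and endocrine list, 6 of 7 members were negative and the camera adjusted p was 0.358, with miR-375-y at -0.10 (SE 0.12) and miR-7-x at -0.48 (SE 0.21). Without control replicate 3 miR-375-y stood at -0.20 and miR-7-x at -0.18. The let-7, miR-100 and miR-125 list had 8 of 13 members positive and a camera adjusted p of 0.555, with miR-100-x at 0.08 (SE 0.10). The hypoxia list, with miR-210-x at 0.04 (SE 0.12) and miR-210-y at -0.16 (SE 0.12), had a camera adjusted p of 0.970. In these 4 lists 0 members passed when adjusted over the list alone by edgeR, with 4 together at an unadjusted p under 0.05.

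The liver and endothelium lists had 2 tested members each and were only described. miR-122-x, the main miRNA of hepatocytes, stood at 1474 ± 415 TPM in controls and 2215 ± 102 TPM after IHNV (SD, n = 3), a log2 fold change of 0.55 (SE 0.17, edgeR adjusted p = 0.205). Its levels were 1267, 1952 and 1202 TPM in control replicates 1, 2 and 3 and 2269, 2280 and 2097 TPM in infected replicates 1, 2 and 3. Control replicate 2 thus lay nearer the infected libraries than the other controls, as it did for the summed families described in mammals and for 6 of the 10 higher calls of the refit, this one included. Leaving out a control favours calls of rows where it lies toward the infected libraries, so the count of 6 is no separate evidence. miR-122-x passed when adjusted over the list alone (edgeR adjusted p = 0.0241) and miR-122-y, at 0.15, did not. The endothelial miR-126-y had a log2 fold change of -0.08 (SE 0.11) and miR-126-x of 0.10 (SE 0.12), and neither passed when adjusted over the list alone.

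**Figure D2:**
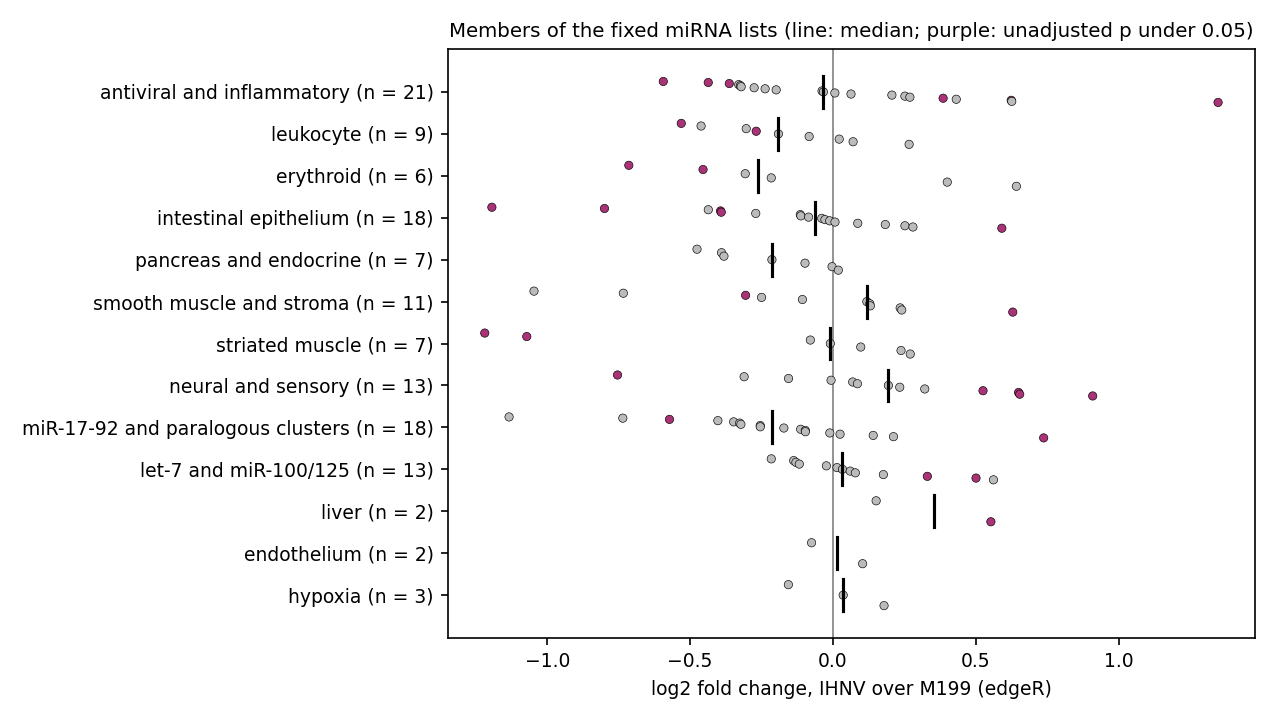
Log2 fold change (edgeR, IHNV over M199) of each tested member of the 13 lists; points are miRNAs, purple where the unadjusted p is under 0.05, and black lines are list medians. The highest point is miR-21-y at 1.35, and the medians lie between -0.26 for the erythroid list and 0.35 for the liver list.

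The third comparison asked whether the 2 arms of a hairpin differed alike. Here a hairpin stands for 1 miRNA name, which carries no letter or copy number and may pool several loci. The 5p arm of miR-21 (TAGCTTATCAGACTGGTGTTGGC) stood at 47496 ± 9317 TPM in controls and 36221 ± 1230 TPM after IHNV, while its 3p arm (CGACAACAGTCTGTAGGCTGT) had the values given above (SD, n = 3). The ratio of 5p to 3p was 38.2 ± 22.7 in controls and 9.81 ± 0.257 after IHNV (SD, n = 3), a change of -1.81 on the log2 scale (SE 0.37, limma adjusted p = 0.110). The ratio of miR-2184 was 3.24 ± 1.02 in controls and 1.52 ± 0.0995 after IHNV (SD, n = 3), a change of -0.84 (SE 0.18, limma adjusted p = 0.110) that ran from -1.02 at a pseudocount of 0.1 to -0.29 at a pseudocount of 10. For both hairpins the ratio was lower in all 3 infected libraries than in any control. Of 89 hairpins, 0 passed by limma and 12 had an unadjusted p under 0.05; no other tool was run on the ratios. Control replicate 3 had a miR-21 ratio of 64.4 against 26.0 and 24.3 in control replicates 1 and 2, and without it 4 hairpins passed, miR-21 at -1.36, miR-2184 at -0.98, miR-221 at 0.61 and miR-27 at 0.55, the last 2 named after their values were seen.

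**Figure D3:**
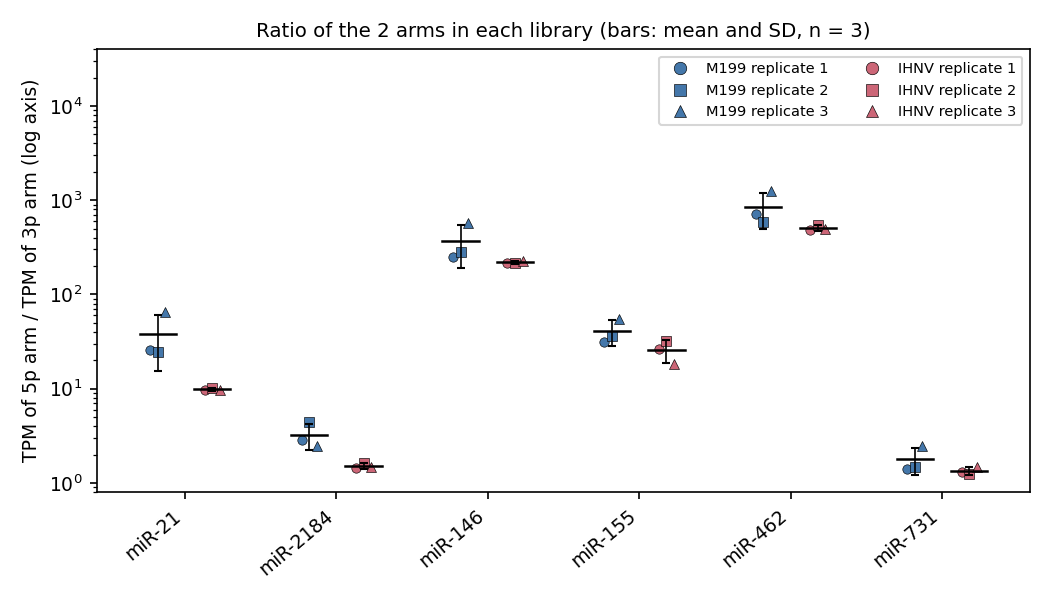
Ratio of 5p to 3p TPM (log axis) of 6 hairpins in each library; points are libraries, lines and bars are the mean and SD of 3 libraries, and all but miR-21 and miR-2184 were chosen after their values were seen. The miR-21 ratio lies between 9.62 and 10.1 in infected libraries and between 24.3 and 64.4 in controls.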

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

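Tests with identical sequences collapsed, library totals only, robust fitting, families described in mammals left out, or an estimated correlation without control replicate 3 were chosen after the data were seen, as was the rule for -z rows in the sum of rows of the same family and arm; the other alternatives were planned. The edgeR count of 0 (104 at an unadjusted p under 0.05) became 21 with DESeq2, 3 with limma-trend on log2(TPM + 10) (miR-21-y, miR-2184-y and the predicted CCTGGATGTGGGTTCCGTCTCC), 1 each without a filter, with known rows only and with rows of the same family and arm summed (miR-21-y each time), and 13 (11 distinct sequences) with the families described in mammals and control replicate 2 left out together. Leaving out 1 library gave 0 to 40 calls: 40 without control replicate 2, 1 without control replicate 3 and 0 otherwise. DESeq2 and the fit without control replicate 2 shared 12 rows. The other 15 of 23 alternatives gave 0, with 52 to 117 rows at an unadjusted p under 0.05. Lists past the threshold by camera numbered 0 to 1 and arm ratios 0 to 4 when 1 library was left out, the 1 and the 4 without control replicate 3. All other alternatives gave 0, among them the lists without control replicate 3 at an estimated correlation (smallest camera adjusted p = 0.407, 0 lists at an unadjusted p under 0.05). The cause of these differences was not tested beyond what stands under the other observations.

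The replicate numbers did not pair the samples: same-numbered libraries had correlations of 0.04, -0.15 and 0.01 in their deviations from the group means. With a replicate block the edgeR count of calls was 0 (88 at an unadjusted p under 0.05), the list count 0 and the arm ratio count 0, and the block changed no other call.

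Values that turned direction were all of lists camera called in no setting or of miRNAs no setting called. As list medians with a turned test direction, the hypoxia list gave 0.0732 with limma-trend on log2(TPM + 10), 0.0326 with DESeq2, -0.0167 with known rows only, -0.00216 with identical sequences collapsed, -0.0623 at an estimated correlation without control replicate 3 and -0.0623 to 0.0838 with 1 library left out. The smooth muscle and stroma list gave -0.0104 without a filter, 0.0673 with known rows only, 0.0801 with identical sequences collapsed and 0.0662 to 0.129 with 1 library left out. The antiviral and inflammatory list gave -0.176 at a minimum of 10 CPM, -0.0875 with known rows only and -0.136 to 0.0894 with 1 library left out, and the striated muscle list 0.0539 at that minimum. As log2 fold changes, miR-192-x gave 0.0119 with limma at each pseudocount and without trend, 0.0514 with the families described in mammals and control replicate 2 left out, and -0.172 to 0.0396 with 1 library left out. miR-1-z gave 0.0306 to 0.0312 with limma at each pseudocount and without trend, and 0.0292 with library totals only. It gave 0.000959 at the minimum of 10 CPM and -0.0660 to 0.0365 with 1 library left out. miR-126-y gave 0.159 after quantile normalization and -0.133 to 0.0270 with 1 library left out, miR-210-x -0.0167 with known rows only, -0.00216 with identical sequences collapsed and -0.0384 to 0.0838 with 1 left out, and miR-199-x -0.218 to 0.10 with 1 left out. miR-210-y gave 0.0565 with rows of the same family and arm summed. Scaling moved the median log2 fold change of all rows by less than 0.1.

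Other values kept their direction but changed in size. Over all alternatives the median log2 fold change of the leukocyte list ran from -0.27 to -0.0474, of the intestinal epithelium list from -0.17 to -0.00232, of the pancreas and endocrine list from -0.45 to -0.0524 and of the miR-17-92 and paralogous clusters list from -0.30 to -0.0784. The log2 fold change of miR-99-x ran from 0.15 to 0.37, of miR-10545-x from -0.95 to -0.45, of miR-144-x from -0.83 to -0.36, of miR-21-x from -0.56 to -0.17, of miR-181-x from -0.27 to -0.10, of miR-7-x from -0.63 to -0.18, of miR-199-z from 0.38 to 0.88 and of miR-206-y from -1.55 to -0.41. The pseudocount of 10 shrank miR-10545-x, miR-144-x, miR-199-z and miR-206-y. Leaving out control replicate 3 shrank miR-21-x (to -0.24), miR-181-x and miR-7-x.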

Other observations

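The tests of miR-21 without control replicate 3, of families described in mammals, of a mislabelled library, of RNA of infected samples, of the loss of any control, of length in control replicate 3 and of the epithelial list in it were chosen only after the results were seen. Intervals below are 95% bootstrap intervals over miRNA rows, apart from that of the miR-21 ratio, which is a limma interval. Bootstrap intervals over rows measure no spread between libraries. Other rows in the authors' deposited table below the filter used here included miR-203-x, whose authors' means were 1.02 TPM in controls and 0.191 TPM after IHNV, the same direction as miR-203-y. DESeq2 also called miR-2184-y, at 3.51 ± 1.13 TPM in controls and 9.46 ± 0.133 TPM after IHNV (SD, n = 3), a log2 fold change of 1.39.

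Chance could not be weighed by regrouping, since the 6 libraries make only 10 splits, too few for a share under 0.05. The real split gave 0 edgeR calls and the highest other split 1; 104 rows with an unadjusted p under 0.05 against 37; 0 lists against 3; and 0 arm ratios against 0.

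In the miR-21 hairpin the 3p arm was higher after IHNV and the 5p arm was not. The ratio of arms does not depend on library scaling, but it was picked by the smallest p of 89 ratios and its change of -1.81 did not pass (adjusted p = 0.110), so scaling was not tested on it. Without control replicate 3 the change was -1.36 (-1.61 to -1.11, adjusted p = 0.000246), which argues against that library as the sole cause. Other 21 nt miRNAs exceeded other 23 nt miRNAs by a median of 0.14 in log2 fold change (0.02 to 0.32), far below the change of the ratio, which argues against length. An arm-specific change after IHNV may stand behind it and stays a hypothesis, since a difference in the processing of single libraries beyond length was not tested. The name miR-21 may also pool several loci, which these rows cannot separate.

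The less abundant arms of the antiviral and inflammatory list were higher relative to their partners in 7 of its 8 hairpins after IHNV, with a median change of 0.54 on the log2 scale against -0.07 for all 89 hairpins. Without control replicate 3 the median was 0.30, and without miR-21 the counts were 6 of 7 with a median of 0.46. The list was fixed before the data were examined, but the split by minor arm was noticed in these same hairpins, so no test of it is given.

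Leaving out control replicate 2 gave 40 calls, 17 of them on the list, written after these calls were seen, of families described in mammals and not in fish. Beyond other known rows, the 43 tested rows of this list were higher in control replicate 2 than in the other controls by 0.69 on the log2 scale (0.60 to 0.79). The 26 of them that were not called were higher by 0.61 (0.46 to 0.69). The 8 listed rows at a mean of 10 TPM or more had a median pairwise correlation of 0.978 across libraries. Listed rows are thus not independent, and these intervals are too narrow. Reads from another organism may account for the 17, with a source not tested and a list from general knowledge that may hold errors. On rows that part control replicates 1 and 3 from 2 infected libraries, with position 0 at those controls and 1 at those infected libraries, the median position of control replicate 2 was 0.632 to 0.694 (0.528 to 0.584 without listed rows) and that of the held-out infected library 0.889 to 1.02 (smallest median difference -0.187, -0.303 to -0.0665), which argues against a mislabelled infected library; leaving out control replicate 1 or 3 gave at most 1 call, which argues against the loss of any control. Control replicate 2 had a mean correlation of 0.989 to the infected libraries and 0.984 to the other controls, control replicate 3 included. By chi-square over degrees of freedom it lay nearer control replicate 1 (41.4) than control replicate 3 (865), and pairs of infected libraries gave 49.1 to 100. On the first principal component it stood at 1.44, against 3.53 to 6.95 for infected libraries and -5.25 and -12.6 for the other controls. RNA of infected samples would put it at 1 common position. On the TPM scale its median position was 0.794 on 35 listed and 0.599 on 46 other rows higher after IHNV (difference 0.195, 0.0432 to 0.328). It was 0.227 for miR-21-y and 0.731 for miR-122-x. These rows were picked by p in a fit without control replicate 2, where rows let in by chance also place it between the groups. The difference therefore cannot decide on such RNA, which stays open. An IHNV effect on the 23 calls not on the list, 16 higher and 7 lower, stays open too. The list may also miss families, so these calls are not cleared of reads from another organism, nor is a refit without the list. Among the 16, miR-191-x, named after its values were seen, stood at 316, 537 and 306 TPM in control replicates 1, 2 and 3. It stood at 625, 622 and 585 TPM in infected replicates 1, 2 and 3. A refit without the listed families and control replicate 2 called 13, 10 higher and 3 lower (the 3 being 1 sequence). Of those 10, with control replicate 2 at log2 positions from -0.658 to 1.02, 8 were higher in it than in both other controls. Leaving it out favours calls of rows where it lies toward the infected libraries, so these positions are no separate evidence on it.

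Control replicate 3 stood apart from the other libraries, at -12.6 on a first principal component that held 44.9% of the variance. Its log2 ratio over the other controls was higher for longer miRNAs (Spearman rho 0.457 across sequences, which are not independent). The next rho in size was -0.375 in control replicate 1, but control replicate 3 is part of the reference there, so the 2 values are linked. In infected libraries, each over the others of its group, rho lay between -0.0467 and 0.0722. Of 23 pairs of longer and shorter forms, 17 had their highest ratio in control replicate 3, where chance gives 3.83 for a library picked beforehand. This library was not picked beforehand, and the pairs come from the same counts. Some pairs share a row or join differently named miRNAs, so they are no independent test. Size selection may therefore have differed. Its epithelial list lay at a median of -0.40 (-0.59 to -0.24), and at -0.30 after rows of the same length were subtracted, so less epithelium in the sample also stays open. For GC content, rho was -0.223 in control replicate 3 against 0.277 in control replicate 2, and it lay between -0.153 and 0.122 in infected libraries. The values of the controls are linked in the same way and are no measure of spread between libraries. A GC trend therefore stays open.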
